A study of Homo sapiens with 60 samples.

How the data were processed

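RNA-seq was done on HepG2 cells, a human hepatocellular carcinoma line, after 24 h with a vehicle, with wortmannin or with water extracts of 6 medicinal herbs. Per the labels, RNA with an integrity number above 7 went into a strand-specific mRNA library kit and was read as 100 bp pairs on an MGI sequencer. The 60 libraries made 20 groups of 3, taken from the labels. The labels give the vehicle as 0.1% DMSO, while the series' design text gives 2% DMSO, so its level is uncertain. Each library also carries a sample code, and the codes fall into 5 sets. The vehicle has a set of its own, wortmannin has another, and 3 further sets hold 2 extracts each (Liriopis with Schisandrae, Longan with Zizyphi, Polygalae with Aucklandiae). What a set stands for is not stated, and every comparison with the vehicle crosses sets, so the high and low doses of an extract, which share a set, were also compared.

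The authors deposited expected counts, that is, estimated numbers of reads or read pairs per gene that need not be whole, in a single table with 1 column per library. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 and the builds hg38 and GRCh38, with no role or order. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Genes on opposite strands of the same place, overlapping genes and near-identical copies are therefore named as uncertain. The table held 60675 genes, of which 57055 were matched to a symbol in the reference. Coordinates are those of GENCODE release 29 on GRCh38.

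Expected counts were rounded to whole numbers. Genes with enough counts were chosen with edgeR's filterByExpr by group, which left 16517 genes, and the untested genes held 0.0532% of all counts. Library sizes were scaled with TMM factors (0.92 to 1.08). A single edgeR quasi-likelihood model with a term for each of the 20 groups was fitted to all 60 libraries (R 4.3.3, edgeR 4.0.16, limma 3.58.1). Each contrast was tested 2-sided and Benjamini-Hochberg adjusted over all tested genes, with a threshold of 0.05. CPM values were computed after TMM scaling, given as mean ± SD of 3 libraries, and log2 fold changes are given with their standard error from the fit. The median log2 fold change over all tested genes lay within 0.00955 of 0 in the 25 comparisons. The labels do not say whether replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

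Comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined. Of 36 lists, 35 had at least 5 tested members and were used, and the markers of fibroblasts and stellate cells (3 of 10 members tested) were not. Lists were tested 2-sided against all other genes with limma's camera on the edgeR model with a preset correlation of 0.01, with adjustment over all lists and contrasts of a family, and again with a correlation estimated from the residuals. Named genes are the 6 largest rises and the 6 largest falls per high dose or wortmannin contrast that passed the test, reached 5 CPM in a group mean and had every treated library beyond every vehicle library. They further include the 3 members with the smallest p of the 5 lists with the smallest camera p, and 14 genes fixed in advance. Genes outside the rule are named as such.

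Alternatives were RLE in place of TMM scaling, no filter on low counts (35717 genes), a stricter filter (at least 1 CPM in 30 libraries, 13152 genes), the replicate number as a block over all libraries or within a code set, DESeq2 1.42.0, a fit of the 6 libraries of a comparison alone, and leaving out each library in turn. A pair of settings was added after the data were seen. The first takes as covariates a library's GC slope, the slope of its log2 deviations on the GC content of genes, and its share of structured RNA such as ribosomal and small nuclear RNA. The other leaves out the 4 libraries with the lowest GC slope: vehicle replicate 1, low-dose Liriopis replicate 1, low-dose Schisandrae replicate 2 and medium-dose Aucklandiae replicate 3. Replicate numbers are given in the labels, which say nothing of what they share. Deviations of same-numbered libraries correlated above 0.1 for all 3 pairs in low-dose Liriopis against the vehicle (r = 0.51, 0.29 and 0.23), high- against low-dose Schisandrae (0.37, 0.15 and 0.32) and high- against low-dose Zizyphi (0.32, 0.55 and 0.16), and in no other comparison.

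The tests were checked on simulated counts with the depth and spread of high-dose Schisandrae against the vehicle (16316 genes). Of 50 genes changed at each size, edgeR called 56% at 1.25-fold, 78% at 1.5-fold, 96% at 2-fold and 98% at 4-fold, with 6 false calls. In that simulation camera called the changed list and 0 of the unchanged lists. Regrouped real libraries gave many calls, so this cannot vouch for camera. Total counts per library ranged from 20.21 to 36.41 M (median 25.765 M), and the common biological coefficient of variation was 0.0707. A count of 0 was given an upper limit of 3 counts over the summed depth of its group, which covers counting error only. No 2 libraries of a group were the same library deposited again, since the chi-square of their counts per degree of freedom was 2.58 or more.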

Results

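Transcript levels were measured by RNA-seq in HepG2 cells, a human hepatocellular carcinoma line that keeps many hepatocyte functions, 24 h after treatment. The series profiled herbs used in a decoction of traditional medicine, each as a water extract at a high, a medium and a low dose, beside a DMSO vehicle and wortmannin at 10 µM as the positive control. Extracts of Liriopis seu Ophiopogonis Tuber, Schisandrae Fructus, Longan Arillus, Zizyphi Semen and Aucklandiae Radix were given at 500, 100 and 20 µg/mL, and Polygalae Radix at 450, 90 and 18 µg/mL, a range set by its toxicity to the cells. Each of the 20 groups had 3 libraries, and total counts per library ran from 20.21 to 36.41 M. Of 60675 genes, 16517 had enough counts for a test. All adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those for gene lists from camera. Comparisons with the vehicle share its 3 libraries, so their overlaps were not compared. Mitochondrially encoded mRNAs took 14.1% ± 1.77 of counts in the vehicle (SD, n = 3) and between 9.11% (low-dose Polygalae) and 13% (high-dose Zizyphi) in the means of the treated groups.

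**Figure D1:**
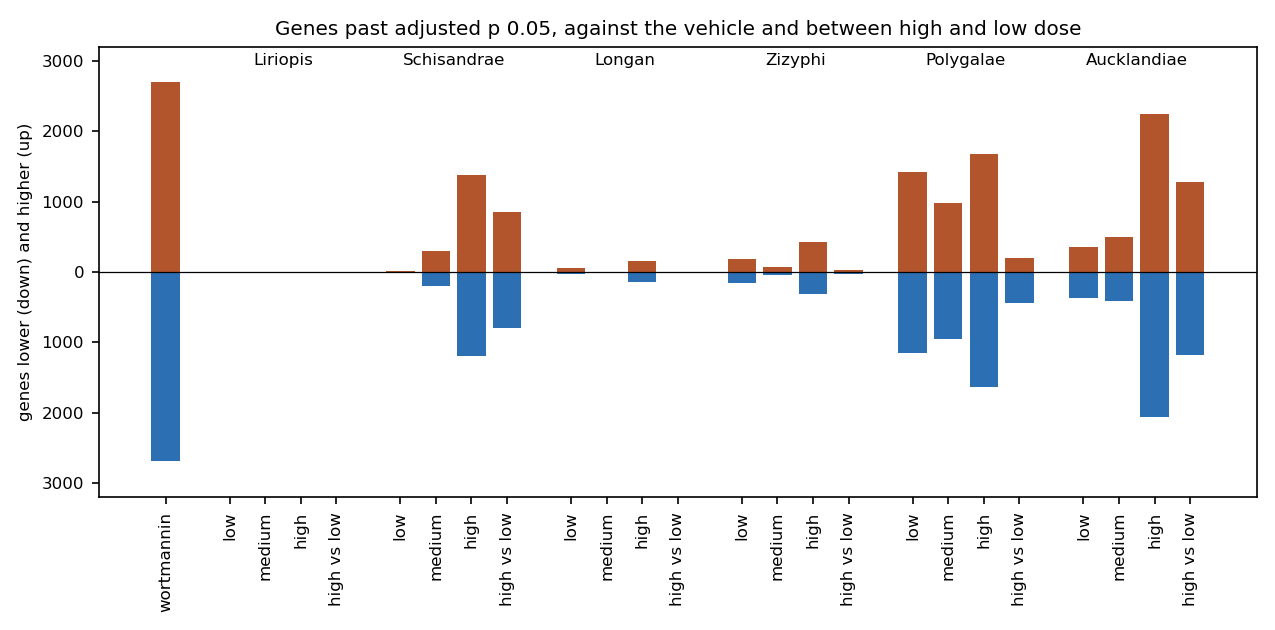
Number of genes with an edgeR adjusted p under 0.05 in each comparison, drawn upward for genes higher and downward for genes lower than in the reference group (3 libraries a group). Totals were 5385 for wortmannin, 4306 for high-dose Aucklandiae, 3326 and 2584 for high- and low-dose Polygalae, 2585 for high-dose Schisandrae and 8 for high-dose Liriopis.

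Wortmannin, an inhibitor of phosphoinositide 3-kinases, was compared with the vehicle as the series' positive control. G6PC1 (ENSG00000131482, chromosome 17, 42900797 to 42913369), the catalytic subunit of glucose-6-phosphatase, rose from 1.66 ± 0.586 to 16.2 ± 2.29 CPM (SD, n = 3), a log2 fold change of 3.3 ± 0.2. IGFBP1 (ENSG00000146678, chromosome 7, 45888357 to 45893668), a secreted binding protein of insulin-like growth factors, rose from 23.9 ± 2.94 to 102 ± 14.3 CPM (log2 fold change 2.1 ± 0.18). Mitotic genes fell, among them PLK1 (ENSG00000166851, chromosome 16, 23677656 to 23690367), a kinase needed for mitotic entry and spindle assembly, from 336 ± 1.7 to 153 ± 9.29 CPM (log2 fold change -1.13 ± 0.06). Their edgeR adjusted p-values were 4.1e-18, 7.4e-13 and 6.8e-21, and all 3 treated libraries lay beyond all 3 vehicle libraries.

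Of 19 FOXO target genes, which these transcription factors switch on when kinase signalling from the insulin receptor is low, 12 rose and 2 fell (13 and 3 adjusted over the list alone; median log2 fold change 0.479, camera adjusted p = 1.17e-06). ERBB3, a receptor of this list, rose by 0.53 ± 0.05. Outside the list, DEPP1, a regulator of autophagy, rose by 1.58 ± 0.09, BDH1, an enzyme of ketone body metabolism, by 1.56 ± 0.08 and MMP11, a matrix metalloproteinase, by 1.43 ± 0.08 on the log2 scale. All 18 genes of the G2 and M phase list fell, also adjusted over the list alone (median -0.792, camera adjusted p = 6.85e-55). CCNB1, the mitotic cyclin, was at -0.98 ± 0.05, the kinesin gene KIF20A at -0.95 ± 0.05 and the proliferation marker MKI67 at -0.74 ± 0.08. All 20 ribosome biogenesis genes fell, also adjusted over the list alone (median -0.501, camera adjusted p = 2.16e-19). NOP2 was at -0.56 ± 0.04, DKC1 at -0.51 ± 0.04 and NOLC1 at -0.41 ± 0.03. Among replication genes 13 of 18 fell and 1 rose, with the same numbers adjusted over the list alone (median -0.21, camera adjusted p = 4.77e-05). RRM2, a ribonucleotide reductase subunit, was at -0.41 ± 0.03, POLA1 at -0.44 ± 0.06 and MCM7 at -0.39 ± 0.05. Heat shock chaperone genes fell for 12 of 16 members (12 fell and 1 rose adjusted over the list alone; median -0.299, camera adjusted p = 1.25e-08). HSP90AA1 was at -0.51 ± 0.06, STIP1 at -0.38 ± 0.04 and FKBP4 at -0.37 ± 0.04. HOXD1, a homeobox factor, fell by 1.52 ± 0.14, SLC6A14, an amino acid transporter, by 1.43 ± 0.07 and DKK1, a secreted Wnt inhibitor, by 1.31 ± 0.1 on the log2 scale.

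Rising lists with wortmannin were PXR and CAR targets, genes of drug metabolism (8 of 9, also adjusted over the list alone; median 0.324, camera adjusted p = 9.61e-05), PPARA and fatty acid oxidation genes (7 rose and 1 fell of 13, 10 and 2 adjusted over the list alone; 0.29, 0.00178), lysosome and autophagy genes (10 rose and 1 fell of 21, 10 and 2 adjusted over the list alone; 0.137, 0.000235) and cholesterol efflux genes (5 of 8, 6 rose and 1 fell adjusted over the list alone; 0.232, 0.00586). Hepatocyte secreted proteins rose for 12 and fell for 1 of 20 genes, the same adjusted over the list alone (median 0.267, camera adjusted p = 0.000326, and adjusted p = 0.325 with an estimated correlation). ALB, the albumin gene, was at 7990 ± 211 CPM against 6660 ± 319 (edgeR adjusted p = 0.014), a call that ended without vehicle replicate 3 (log2 fold change 0.24). NRF2 targets fell for 12 of 19 genes (13 adjusted over the list alone; median -0.201, camera adjusted p = 0.00052, and adjusted p = 0.102 with an estimated correlation). NQO1, a quinone reductase, was at -0.24 ± 0.04 and HMOX1, heme oxygenase, at -0.29 ± 0.07. Immediate early genes fell for 9 and rose for 1 of 16 genes, the same adjusted over the list alone (median -0.336, camera adjusted p = 0.0013, and adjusted p = 0.179 with an estimated correlation). CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 0.92 ± 0.1 on the log2 scale, to 13.7 ± 0.269 CPM.

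In all, 5385 genes changed with wortmannin by edgeR (32.6% of those tested), 2703 upward and 2682 downward, of which 232 rose and 65 fell at least 2-fold. AC009086.2, which overlaps QPRT, and AC011511.4, which overlaps FDX2 and RAVER1, also stood among the largest changes and are uncertain, since shared reads could belong to either gene. The call of AC009086.2 ended without vehicle replicate 1 (0.8) or wortmannin replicates 1 or 2 (1.36 and 1.41), and that of AC011511.4 without vehicle replicates 1 or 2 (-1.02 and -1.23) or wortmannin replicates 1, 2 or 3 (-1.24, -1.19 and -1.19). EVA1A-AS, an antisense gene and so uncertain as well, fell by 1.16 ± 0.19 on the log2 scale.

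Aucklandiae Radix at 500 µg/mL raised the genes of the NRF2 response, which codes for enzymes that reduce or conjugate reactive compounds. AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408), an aldo-keto reductase, rose from 38.1 ± 3.01 to 229 ± 0.217 CPM (SD, n = 3), a log2 fold change of 2.59 ± 0.05. PTGR1 (ENSG00000106853, chromosome 9, 111549722 to 111599893), a reductase of lipid aldehydes and eicosanoids, rose from 11.1 ± 0.395 to 71.6 ± 2.73 CPM (2.69 ± 0.09), and NQO1 (ENSG00000181019, chromosome 16, 69706996 to 69726951) from 340 ± 6.56 to 686 ± 9.45 CPM (1.01 ± 0.04). All 19 tested NRF2 targets rose, also adjusted over the list alone (median 0.894, camera adjusted p = 3.61e-108). Mitotic genes and metallothioneins, the small zinc-binding proteins, fell. The edgeR adjusted p-values of the 3 genes were 1.7e-36, 1.5e-28 and 2.6e-23.

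AKR1C1 and AKR1C2, further aldo-keto reductases, reached 2160 ± 52.5 and 995 ± 26 CPM against 429 ± 14 and 191 ± 4.79 in the vehicle, and the glutathione transferase gene GSTA2 reached 35.1 ± 2.78 against 5.86 ± 0.147 CPM. These genes have close copies, so the split of reads within each family is uncertain. HMOX1 rose by 0.95 ± 0.06 and SLC5A11, a sodium-coupled transporter of inositol, by 2.33 ± 0.16 on the log2 scale. Lysosome and autophagy genes rose for 13 of 21 members (14 adjusted over the list alone; median 0.335, camera adjusted p = 1.11e-13). The autophagy receptor SQSTM1 was at 1.05 ± 0.04, the galactosidase gene GLA at 0.9 ± 0.07 and the protease gene CTSB at 0.51 ± 0.04. Glycolysis genes rose for 13 of 16 (15 adjusted over the list alone; 0.486, 1.23e-11). GPI was at 0.47 ± 0.04, ENO1 at 0.56 ± 0.06 and ALDOA at 0.55 ± 0.06. Hypoxia targets rose for 13 of 16, also adjusted over the list alone (median 0.432, camera adjusted p = 3.78e-10). NDRG1 was at 1.31 ± 0.1, BNIP3 at 0.69 ± 0.07 and the histone demethylase gene KDM3A at 0.54 ± 0.06.

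All 18 genes of the G2 and M phase list fell at this dose, also adjusted over the list alone (median -0.582, camera adjusted p = 1.31e-34). PLK1 was at -0.84 ± 0.06, MKI67 at -0.77 ± 0.08, KIF20A at -0.71 ± 0.05 and TOP2A, a topoisomerase of dividing cells, at -0.7 ± 0.05. Replication genes fell for 11 and rose for 1 of 18, the same adjusted over the list alone (-0.188, 8.05e-05). Cholesterol synthesis and uptake genes fell for 17 of 23 (18 adjusted over the list alone; -0.231, 3.7e-09), HMGCS1, which makes hydroxymethylglutaryl-CoA, by 0.65 ± 0.05 on the log2 scale, and fatty acid synthesis genes fell for 10 of 13, also adjusted over the list alone (-0.217, 2.46e-09). Metallothioneins and zinc response genes fell for 8 and rose for 1 of 9 members, the same adjusted over the list alone (median -1.661, camera adjusted p = 1.63e-07). MT1G went from 54.8 ± 1.68 to 15.2 ± 1.49 CPM and MT2A from 197 ± 11.4 to 62 ± 5.56 CPM. MT1E and MT1F were at log2 fold changes of -1.78 ± 0.22 and -1.66 ± 0.21, and reads may be shared between these near-identical genes. IGFBP1 rose by 2.04 ± 0.18, CYP1A1 by 1.18 ± 0.09 and TRIB3 by 0.2 ± 0.06 on the log2 scale, the last a call that ended without vehicle replicate 1 (0.14). CDKN1A, an inhibitor of cell cycle kinases, rose by 0.24 ± 0.08, and its call ended without vehicle replicates 1 or 3 (0.2 and 0.22) or high-dose replicates 2 or 3 (0.18 and 0.21).

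Smaller list changes at this dose were rises of PXR and CAR targets (4 rose and 1 fell of 9, the same adjusted over the list alone; median 0.229, camera adjusted p = 2.17e-05), PPARA and fatty acid oxidation genes (7 rose and 4 fell of 13, the same adjusted over the list alone; 0.316, 0.00287), AHR targets (2 rose and 1 fell of 6, the same adjusted over the list alone; 0.034, 0.00109) and iron handling genes (5 of 11, also adjusted over the list alone; 0.058, 0.0214), and a fall of hepatocyte transcription factors (6 fell and 1 rose of 13, 7 and 1 adjusted over the list alone; -0.299, 0.00227). Mitochondrially encoded mRNAs fell for 9 of 13 (13 adjusted over the list alone; median -0.608, camera adjusted p = 0.000555, and adjusted p = 0.417 with an estimated correlation). By edgeR 4306 genes changed (26.1%), 2242 upward and 2064 downward, 173 and 116 of them at least 2-fold. Among the largest falls, AC008622.2, an antisense gene, and AL132780.3, which overlaps HAUS4 and AJUBA, are uncertain. The call of AC008622.2 ended without vehicle replicates 1, 2 or 3 (-1.68, -1.74 and -1.75) or high-dose replicates 2 or 3 (-1.52 and -1.67).

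Between the high and low doses of Aucklandiae, which share a code set, all 19 NRF2 targets were higher at the high dose, also adjusted over the list alone (median 0.673, camera adjusted p = 2.21e-102). AKR1B10 differed by 1.81 ± 0.05, PTGR1 by 2.37 ± 0.09, HMOX1 by 1.02 ± 0.06 and NQO1 by 0.61 ± 0.04 on the log2 scale. All 18 genes of the G2 and M phase list were lower, also adjusted over the list alone (-0.504, 2.34e-44), and so were 17 of 23 cholesterol genes (18 adjusted over the list alone; -0.247, 9.28e-14) and 7 of 9 metallothionein list members, with 1 higher (8 and 1 adjusted over the list alone; -1.353, 3.86e-09). Hypoxia targets were higher for 7 of 16 genes (9 adjusted over the list alone; 0.262, camera adjusted p = 0.000248, and adjusted p = 0.0683 with an estimated correlation). AKR1B10 rose at every dose, by 2.59 ± 0.05 at the high, 1.53 at the medium and 0.78 at the low dose against the vehicle. HMOX1 was at log2 fold changes of -0.05 and -0.07 at the medium and low doses (edgeR adjusted p = 0.76 and 0.63). In all, 2462 genes differed between high and low dose, 1283 higher and 1179 lower (1525 from the 6 libraries alone, 3718 with the covariates). Against the vehicle 911 genes changed at the medium and 735 at the low dose. The medium count was 485, 557 and 603 without vehicle replicates 1, 2 and 3, and 477 and 303 without medium-dose replicates 2 and 3. The low count was 121 and 476 without vehicle replicates 1 and 2, and 371 and 222 without low-dose replicates 2 and 3.

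**Figure D2:**
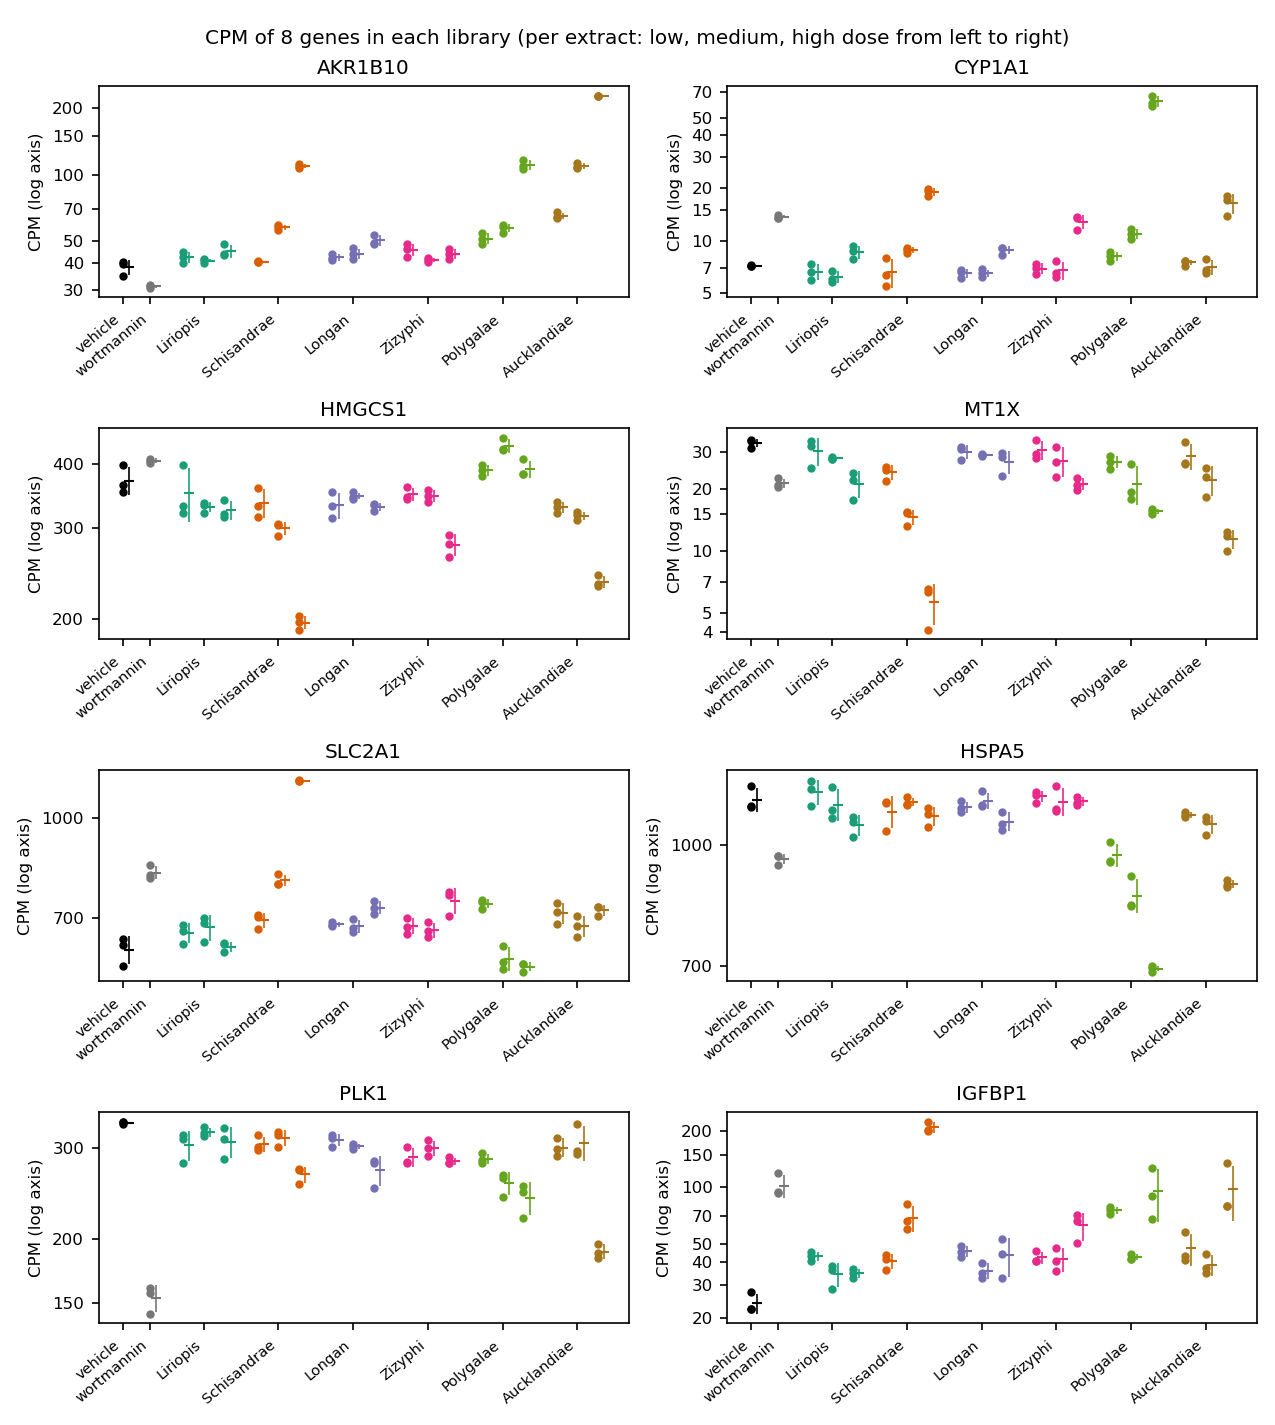
CPM of 8 genes in each of the 60 libraries on a log axis, with 3 points per group and the doses of an extract running from low to high. AKR1B10 sits at 229 CPM with high-dose Aucklandiae and 38.1 CPM in the vehicle, CYP1A1 at 62.1 CPM with high-dose Polygalae and 7.2 CPM in the vehicle, and MT1X at 5.62 CPM with high-dose Schisandrae and 33.4 CPM in the vehicle.

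Schisandrae Fructus at 500 µg/mL lowered the genes of sterol and fatty acid synthesis and the metallothioneins. HMGCS1 (ENSG00000112972, chromosome 5, 43289395 to 43313512) fell from 371 ± 23.6 to 197 ± 5.99 CPM (SD, n = 3), a log2 fold change of -0.91 ± 0.05. MT1X (ENSG00000187193, chromosome 16, 56682424 to 56684196) fell from 33.4 ± 1.66 to 5.62 ± 1.3 CPM (-2.57 ± 0.15). SLC2A1 (ENSG00000117394, chromosome 1, 42925375 to 42959176), a glucose transporter, rose from 626 ± 30.8 to 1140 ± 3.75 CPM (0.87 ± 0.04). The edgeR adjusted p-values were 2.7e-18, 5.3e-18 and 5.5e-22, and for each gene all 3 treated libraries lay beyond all 3 vehicle libraries.

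Cholesterol synthesis and uptake genes fell for 21 of 23 members and rose for 1, the same adjusted over the list alone (median -0.528, camera adjusted p = 8.32e-47), among them SQLE, squalene epoxidase, at -0.64 ± 0.04 and ACAT2 at -0.61 ± 0.05. All 13 fatty acid synthesis genes fell, also adjusted over the list alone (median -0.355, camera adjusted p = 7.1e-25). ACSS2, an acetyl-CoA synthetase, was at -0.86 ± 0.04, the desaturase gene FADS2 at -0.59 ± 0.04 and GPAM at -0.66 ± 0.05. Glycolysis genes rose for 15 of 16 (16 adjusted over the list alone; 0.532, 4.79e-26). ALDOA was at 0.64 ± 0.06, GPI at 0.49 ± 0.04 and PKM at 0.39 ± 0.04. Hypoxia targets rose for 12 of 16, also adjusted over the list alone (0.524, 1.88e-24). PDK1, which inhibits pyruvate dehydrogenase, was at 0.95 ± 0.08 and NDRG1 at 0.91 ± 0.1.

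Of the metallothionein and zinc response list, 8 genes fell and 1 rose, the same adjusted over the list alone (median -2.566, camera adjusted p = 2.25e-22). MT1G fell from 54.8 ± 1.68 to 4.84 ± 1.17 CPM, MT1F from 27 ± 2.14 to 2.73 ± 0.265 CPM, MT1E from 94.7 ± 4.5 to 14.7 ± 2.22 CPM and MT2A from 197 ± 11.4 to 51.3 ± 9.95 CPM, with reads possibly shared between copies. The summed level of 18 annotated metallothionein genes and pseudogenes was 409 ± 13.4 CPM in the vehicle and 79.9 ± 14.6 CPM at the high dose. The member that rose was SLC39A10, a zinc importer that falls when zinc is plentiful, at 1.2 ± 0.08.

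Immediate early genes rose for 12 of 16 members at this dose (13 adjusted over the list alone; median 0.737, camera adjusted p = 2.28e-15), TGF-beta and matrix genes for 7 of 12 (7 rose and 1 fell adjusted over the list alone; 0.218, 6.86e-09) and NF-kB and cytokine genes for 6 of 11 (6 rose and 1 fell adjusted over the list alone; 0.208, 5.62e-07). NRF2 targets rose for 12 and fell for 1 of 19, the same adjusted over the list alone (0.357, 8.14e-22), AKR1B10 by 1.53 ± 0.05 and NQO1 by 0.51 ± 0.04 on the log2 scale. IGFBP1 rose from 23.9 ± 2.94 to 210 ± 13.7 CPM (3.14 ± 0.19), LCN15, a lipocalin, by 2.63 ± 0.25 and CYP1A1 by 1.39 ± 0.09, while KNG1, the kininogen gene, fell by 1.23 ± 0.17 on the log2 scale. Genes of the G2 and M phase fell for 10 of 18 (15 adjusted over the list alone; -0.189, 1.63e-07), MKI67 by 0.32 ± 0.08, and hepatocyte transcription factors for 5 of 13 (6 fell and 1 rose adjusted over the list alone; -0.241, 0.000727). Also called upward were ATF4 targets, genes of amino acid stress (7 of 20, 8 adjusted over the list alone; 0.116, 3.11e-05), lysosome genes (7 rose and 2 fell of 21, 10 and 3 adjusted over the list alone; 0.144, 5.09e-06), FOXO targets (6 rose and 1 fell of 19, 7 and 1 adjusted over the list alone; 0.141, 0.00298), AHR targets (2 rose and 1 fell of 6, the same adjusted over the list alone; 0.01, 0.000988) and PXR and CAR targets (3 rose and 2 fell of 9, the same adjusted over the list alone; 0.1, 0.00351). The leukocyte markers had 1 gene up and 1 down of 5, the same adjusted over the list alone, and their median of -0.095 and mean of 0.003 differed in sign from each other while the test called them upward (camera adjusted p = 0.0204).

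By edgeR 2585 genes changed at the high dose (15.7%), 1387 upward and 1198 downward, 95 and 67 of them at least 2-fold, and 4177 genes passed with GC slope and structured RNA share as covariates. RGPD5, a member of a family of near-identical copies, and AL583722.2, an antisense gene, were among the largest rises and are uncertain. The call of RGPD5 ended without vehicle replicates 1, 2 or 3 (3.08, 2.85 and 2.98) or high-dose replicate 1 (2.03), and that of AL583722.2 without vehicle replicate 1 (1.25) or high-dose replicate 1 (1.79).

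Between high and low dose of Schisandrae, cholesterol genes were lower for 21 of 23 members and higher for 1, the same adjusted over the list alone (median -0.571, camera adjusted p = 3.04e-64). HMGCS1 was at -0.77 ± 0.05 and SQLE at -0.61 ± 0.04. Fatty acid synthesis genes were lower for 12 of 13 (13 adjusted over the list alone; -0.401, 3.58e-37), and the metallothionein list for 7 of 9 with 1 higher (8 and 1 adjusted over the list alone; -2.088, 2.14e-20). Immediate early genes were higher for 12 of 16 (16 adjusted over the list alone; 0.754, 1.96e-24) and glycolysis genes for 12 of 16 (14 adjusted over the list alone; 0.35, 3.04e-18). IGFBP1 differed by 2.38 ± 0.18 on the log2 scale. In all, 1650 genes differed, 858 higher and 792 lower (2797 with the covariates). At the medium dose 493 genes changed against the vehicle and at the low dose 12. MT1X was at -1.2 at the medium dose (edgeR adjusted p = 4e-08) and at -0.48 at the low dose (0.14). The medium count was 129 without vehicle replicate 1, and 195 and 117 without medium-dose replicates 2 and 3. The low count was 1, 0 and 7 without vehicle replicates 1, 2 and 3 and 3, 3 and 0 without low-dose replicates 1, 2 and 3.

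Polygalae Radix at 450 µg/mL induced CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610) from 7.2 ± 0.0444 to 62.1 ± 4.36 CPM (SD, n = 3), a log2 fold change of 3.11 ± 0.09. SQSTM1 (ENSG00000161011, chromosome 5, 179806398 to 179838078) rose from 197 ± 8.63 to 466 ± 7.93 CPM (1.24 ± 0.04), and HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241330), the main chaperone of the endoplasmic reticulum, fell from 1140 ± 40.6 to 694 ± 5.63 CPM (-0.72 ± 0.04). NRF2 targets and lysosomal genes rose together. The edgeR adjusted p-values of these 3 genes were 2.6e-30, 1.4e-28 and 5.6e-19.

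NRF2 targets rose for 11 of 19 genes (13 rose and 1 fell adjusted over the list alone; median 0.426, camera adjusted p = 1.31e-34). AKR1B10 was at 1.55 ± 0.05, OSGIN1 at 1.12 ± 0.07, AKR1C1 at 0.91 ± 0.06 and NQO1 at 0.55 ± 0.04. Lysosome and autophagy genes rose for 15 of 21 (16 adjusted over the list alone; 0.253, 2.11e-21). GLA was at 0.68 ± 0.07 and the sialidase gene NEU1 at 0.56 ± 0.05. Of the 17 endoplasmic reticulum chaperone genes 12 fell and 2 rose, the same adjusted over the list alone (median -0.369, camera adjusted p = 8.21e-23). PDIA4, a disulfide isomerase, was at -0.68 ± 0.04 and HYOU1 at -0.66 ± 0.04. AHR targets rose for 2 of 6 (4 adjusted over the list alone; 0.448, 2.1e-17), CYP1A1 and NQO1, while ALDH3A1 at 0.78 ± 0.29 did not pass (edgeR adjusted p = 0.05), except without high-dose replicates 1 or 2 (0.96 and 0.88). Genes of the G2 and M phase fell for 16 of 18 (17 adjusted over the list alone; -0.373, 1.58e-18), with TOP2A and PLK1 at -0.49 ± 0.05 and -0.49 ± 0.06 and KIF20A at -0.47 ± 0.05. Cholesterol synthesis and uptake genes rose for 15 of 23 (16 adjusted over the list alone; median 0.229, camera adjusted p = 1.36e-08). HMGCS1, at 0.07 ± 0.05, did not pass.

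Also at this dose, ATF4 targets rose for 9 and fell for 2 of 20 genes, the same adjusted over the list alone (median 0.239, camera adjusted p = 0.000104). TRIB3 was at 0.62 ± 0.06, and PXR and CAR targets rose for 4 and fell for 1 of 9 (6 and 1 adjusted over the list alone; 0.242, 3.02e-05). Heat shock chaperone genes fell for 7 of 16 (8 adjusted over the list alone; -0.184, 2.84e-05), replication genes for 6 of 18, also adjusted over the list alone (-0.103, 0.00298), and the metallothionein list for 7 of 9 with 1 rise, the same adjusted over the list alone (-1.103, 0.000119). MT2A was at -1.12 ± 0.23. Hypoxia targets rose for 9 of 16 (10 adjusted over the list alone; 0.329, camera adjusted p = 8.74e-05, and adjusted p = 0.0522 with an estimated correlation). Hepatocyte secreted proteins fell for 9 of 20 (9 fell and 1 rose adjusted over the list alone; -0.227, camera adjusted p = 7.71e-06, and adjusted p = 0.213 with an estimated correlation). Mitochondrially encoded mRNAs fell for 9 of 13 (13 adjusted over the list alone; -0.607, camera adjusted p = 3.92e-05, and adjusted p = 0.336 with an estimated correlation), and their share of counts was 10.1% ± 0.993 against 14.1% ± 1.77 in the vehicle. IGFBP1 rose to 95.4 ± 30.1 CPM (2 ± 0.18). IRS2, an insulin receptor substrate at 0.431 ± 0.0347 CPM, rose by 1.36 ± 0.48, a call that ended without vehicle replicate 1 (0.85) or high-dose replicates 1, 2 or 3 (1.34, 1.3 and 1.41).

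The gene AC008738.3, on the strand opposite CEBPA and therefore uncertain, had 0 counts in all vehicle libraries and 5.37 ± 1.46 CPM at the high dose. Against the limit of 3 counts over the vehicle's summed depth (0.0447 CPM) it was at least 120-fold higher. Of the other 11 largest changes, AL583722.2, AC093484.3 and AC008622.2 are antisense genes, AC009086.2, AL132780.3, CDRT4 and AC011558.1 overlap other genes, and all 7 are uncertain. The calls of AL583722.2, AC009086.2 and AL132780.3 ended without vehicle replicate 1 (1.07, 1.07 and -0.98), that of AL583722.2 also without high-dose replicate 2 (1.63), and that of CDRT4 without high-dose replicate 1 (-1.47). By edgeR 3326 genes changed (20.1%), 1685 upward and 1641 downward, 88 and 73 of them at least 2-fold, and 2200 without vehicle replicate 1. TMEM160, a mitochondrial membrane protein, rose by 1.89 ± 0.34, and ENSG00000282955, which has no symbol or coordinates in the annotation used, was at -1.33 ± 0.31. HMOX1 rose by 0.28 ± 0.07 and MKI67 was at -0.54 ± 0.08, both past the test.

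Between the high and low doses of Polygalae, CYP1A1 differed by 2.94 ± 0.09 on the log2 scale, and AHR targets were higher for 2 of 6 genes (4 adjusted over the list alone; median 0.345, camera adjusted p = 2.24e-33). NRF2 targets were higher for 10 of 19 (11 higher and 1 lower adjusted over the list alone; 0.323, 3.47e-39) and ER chaperone genes lower for 10 of 17 (12 adjusted over the list alone; -0.314, 3.86e-28). HSPA5 was at -0.48 ± 0.04. Glycolysis genes were lower for 5 of 16 (7 adjusted over the list alone; -0.15, 1.16e-07), and genes of the G2 and M phase for 7 of 18 (10 adjusted over the list alone; -0.165, 3.89e-12). The cholesterol list was not called between these doses. In all, 649 genes differed, 203 higher and 446 lower at the high dose (370 without high-dose replicate 2, 394 without low-dose replicate 2, 1307 with the covariates). Against the vehicle 2584 genes changed at the low dose and 1926 at the medium dose. CYP1A1 was at 0.6 at the medium dose (edgeR adjusted p = 2.7e-05) and at 0.17 at the low dose (0.26), while IGFBP1 was at 0.82 and 1.65 and SQSTM1 at 0.75 and 0.78. The medium count was 1005 without vehicle replicate 1 and 2969, 867 and 1075 without medium-dose replicates 1, 2 and 3. The low count was 1208 without vehicle replicate 1 and 1193 without low-dose replicate 2.

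Zizyphi Semen at 500 µg/mL raised IGFBP1 from 23.9 ± 2.94 to 62.5 ± 10.7 CPM (SD, n = 3), a log2 fold change of 1.39 ± 0.18, and CYP1A1 from 7.2 ± 0.0444 to 12.8 ± 1.15 CPM (0.84 ± 0.1). HAMP (ENSG00000105697, chromosome 19, 35280716 to 35285143), which codes for the iron-regulating hormone hepcidin, fell from 22.8 ± 1.3 to 11.2 ± 1.06 CPM (-1.02 ± 0.16), and SCNN1A, a subunit of the epithelial sodium channel, from 25.4 ± 2.17 to 17.4 ± 0.67 CPM (-0.54 ± 0.07). The edgeR adjusted p-values of the 4 genes were 2.2e-06, 3.4e-07, 6.7e-05 and 2e-06.

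Hypoxia targets rose for 9 of 16 genes (11 adjusted over the list alone; median 0.276, camera adjusted p = 9.34e-14), with NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022) at 0.69 ± 0.1, KDM3A at 0.36 ± 0.06 and SLC2A1 at 0.25 ± 0.04. Glycolysis genes rose for 7 of 16 (9 adjusted over the list alone; 0.254, 2.8e-14). PGK1 was at 0.35 ± 0.06, PGAM1 at 0.3 ± 0.05 and GPI at 0.27 ± 0.04. PFKFB4, which makes a regulator of glycolysis, rose by 0.76 ± 0.14. Like that of IGFBP1, this rise cannot be told from an offset of the vehicle's code set in this contrast. Genes of the G2 and M phase fell for 10 of 18 (13 adjusted over the list alone; -0.187, 2.05e-12), PLK1 by 0.25 ± 0.06, fatty acid synthesis genes for 7 of 13 (9 adjusted over the list alone; -0.19, 6.63e-11), ELOVL6 by 0.29 ± 0.04, FADS2 by 0.27 ± 0.04 and ACSS2 by 0.18 ± 0.04, and cholesterol genes for 6 of 23 (7 adjusted over the list alone; -0.148, 4.29e-10), HMGCS1 by 0.41 ± 0.05 and SQLE by 0.25 ± 0.04 on the log2 scale. Lysosome genes rose for 6 of 21 (7 adjusted over the list alone; 0.141, 3.28e-06), PPARA genes for 3 of 13, also adjusted over the list alone (0.182, 0.00149), NF-kB genes for 2 of 11 (5 adjusted over the list alone; 0.141, 0.00328) and PXR and CAR targets for 2 of 9 (3 adjusted over the list alone; 0.047, 0.0109). The metallothionein list fell for 2 of 9 (6 fell and 1 rose adjusted over the list alone; -0.621, 1.42e-05), MT1X by 0.67 ± 0.13 on the log2 scale. Hepatocyte secreted proteins rose for 5 of 20 (7 adjusted over the list alone; 0.13, camera adjusted p = 0.000109, and adjusted p = 0.296 with an estimated correlation).

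SLC22A18, an organic cation transporter, rose by 0.81 ± 0.15 on the log2 scale. Several named calls ended in single omissions: CCNA2 (-0.18) and CYP51A1 (-0.17) without vehicle replicate 1, CYP51A1 also without high-dose replicate 3 (-0.18), AURKA without high-dose replicate 1 (-0.18), MKI67 without vehicle replicate 1 (-0.29) or high-dose replicate 1 (-0.3), GLTPD2 without vehicle replicate 1 (0.73) or high-dose replicate 2 (0.62), and MT1G without vehicle replicate 1 (-0.83) or high-dose replicates 1 or 3 (-0.74 and -0.78). RAB43, a small GTPase gene, was at 0.75 ± 0.2. RAB43 lost its call without vehicle replicates 1 or 3 (0.67 and 0.76) or high-dose replicates 1 or 3 (0.65 and 0.67). AL121594.1, which overlaps PSMA6 and KIAA0391, was at -1.01 ± 0.31 and AC008738.7, a 3' overlapping gene, at -0.54 ± 0.16, and both are uncertain. Their calls ended without vehicle replicates 1, 2 or 3 (-0.94, -1.02 and -1.06) or high-dose replicates 2 or 3 (-0.61 and -1.16) for the first, and without vehicle replicates 1, 2 or 3 (-0.53, -0.55 and -0.55) or high-dose replicates 1, 2 or 3 (-0.57, -0.43 and -0.63) for the other. By edgeR 730 genes changed (4.42%), 422 upward and 308 downward, 18 and 3 of them at least 2-fold. The count was 195 without vehicle replicate 1, and 420, 469 and 383 without high-dose replicates 1, 2 and 3. It was 230 without the 4 libraries of lowest GC slope, 173 from the 6 libraries alone and 1442 with GC slope and structured RNA share as covariates.

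Between high and low dose of Zizyphi, cholesterol genes were lower for 4 of 23 members (15 adjusted over the list alone; median -0.177, camera adjusted p = 2.99e-25) and fatty acid synthesis genes for 4 of 13 (8 adjusted over the list alone; -0.18, 7.97e-19). HMGCS1 was at -0.33 ± 0.05. CYP1A1 differed by 0.9 ± 0.09 and HAMP by -0.98 ± 0.16. Hypoxia targets had 0 of 16 genes past edgeR's test (2 higher adjusted over the list alone; 0.115, camera adjusted p = 0.000112, and adjusted p = 0.0561 with an estimated correlation). In all, 58 genes differed, 35 higher and 23 lower. The count was 38 and 23 without high-dose replicates 1 and 3, 23 and 35 without low-dose replicates 1 and 3, 3 from the 6 libraries alone, 207 with no filter and 216 with the covariates. Against the vehicle 116 genes changed at the medium and 346 at the low dose. The medium count was 1 and 71 without vehicle replicates 1 and 2 and 19 and 8 without medium-dose replicates 2 and 3. The low count was 29 and 169 without vehicle replicates 1 and 2 and 26 and 206 without low-dose replicates 1 and 3.

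Longan Arillus at 500 µg/mL raised AKR1B10 from 38.1 ± 3.01 to 50.5 ± 2.68 CPM (SD, n = 3), a log2 fold change of 0.41 ± 0.05, and NQO1 from 340 ± 6.56 to 420 ± 17.9 CPM (0.3 ± 0.04). NRF2 targets rose for 6 of 19 genes (7 adjusted over the list alone; median 0.217, camera adjusted p = 2.44e-09), AKR1C1 among them by 0.37 ± 0.06. PLK1 fell from 336 ± 1.7 to 272 ± 18.2 CPM (-0.31 ± 0.06), and genes of the G2 and M phase fell for 4 of 18 (11 adjusted over the list alone; -0.167, 1.36e-10). The edgeR adjusted p-values of the 4 genes were 2.5e-05, 8.9e-05, 4e-04 and 0.0016. No call ended with a single library left out. None of the 4 passed between high and low dose, so they may reflect an offset of the vehicle's code set.

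Hypoxia targets rose for 3 of 16 genes (9 adjusted over the list alone; median 0.213, camera adjusted p = 6.59e-10), glycolysis genes for 3 of 16 (6 adjusted over the list alone; 0.146, 2.73e-06) and lysosome genes for 3 of 21 (6 adjusted over the list alone; 0.117, 3.34e-06). SQSTM1 was at 0.24 ± 0.04. Ribosome biogenesis genes fell for 2 of 20 (7 adjusted over the list alone; -0.109, 3.07e-05), PPARA genes rose for 2 of 13, also adjusted over the list alone (0.116, 0.00663), and PXR and CAR targets for 1 of 9, also adjusted over the list alone (0.152, 0.0131). Mitochondrially encoded mRNAs had 0 of 13 genes past edgeR's test, also adjusted over the list alone (-0.327, camera adjusted p = 0.000401, and adjusted p = 0.407 with an estimated correlation), at 11.9% ± 1.58 of counts. IGFBP1 rose by 0.86 ± 0.18 on the log2 scale, a call that ended without vehicle replicate 1 (0.8) or high-dose replicate 3 (0.68). At the low dose IGFBP1 was at 0.93 (edgeR adjusted p = 0.015), and it differed by -0.07 ± 0.17 between high and low dose (edgeR adjusted p = 1). The calls of SLC2A1, KDM3A, PFKFB4, SLC22A18, ZC3H12D and GPATCH11 ended without vehicle replicate 1, at 0.18, 0.24, 0.6, 0.64, 0.55 and -0.27 in place of 0.22, 0.28, 0.63, 0.74, 0.66 and -0.39. HAMP was at 15 ± 1.24 against 22.8 ± 1.3 CPM (edgeR adjusted p = 0.035). HAMP lost its call without any 1 of the 6 libraries (-0.63, -0.61 and -0.55 for vehicle replicates 1, 2 and 3, -0.54, -0.66 and -0.59 for high-dose replicates 1, 2 and 3).

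Further genes that the naming rule picked for Longan passed in the fit of all libraries but not in every fit with a library left out. COL7A1, a collagen gene, was at 0.77 ± 0.19. COL7A1 lost its call without vehicle replicates 1, 2 or 3 (0.69, 0.84 and 0.79) or high-dose replicates 1 or 2 (0.69 and 0.76). NME3 was at 0.72 ± 0.18. NME3 lost its call without vehicle replicates 1 or 3 (0.51 and 0.74) or high-dose replicates 1, 2 or 3 (0.74, 0.7 and 0.74). AC026362.1 was at 0.69 ± 0.17 and lost its call without vehicle replicates 2 or 3 (0.54 and 0.69) or high-dose replicate 1 (0.58). ZNF619 was at -0.49 ± 0.12. ZNF619 lost its call without vehicle replicates 1 or 2 (-0.48 and -0.45) or high-dose replicates 1, 2 or 3 (-0.55, -0.53 and -0.38). PPP1R18 was at -0.38 ± 0.09 and lost its call without vehicle replicates 1 or 2 (-0.39 and -0.35) or high-dose replicate 1 (-0.26). NDRG1 was at 0.45 ± 0.1. NDRG1 lost its call without vehicle replicates 1 or 2 (0.44 and 0.38) or high-dose replicate 3 (0.41). GPI was at 0.15 ± 0.04. GPI lost its call without vehicle replicates 1 or 2 (0.14 and 0.14) or high-dose replicates 1, 2 or 3 (0.16, 0.16 and 0.13). PGK1 was at 0.22 ± 0.06. PGK1 lost its call without vehicle replicates 1 or 2 (0.18 and 0.22) or high-dose replicates 1, 2 or 3 (0.24, 0.23 and 0.2). NPC1, a lysosomal cholesterol transporter, was at 0.21 ± 0.05. NPC1 lost its call without vehicle replicates 1 or 2 (0.19 and 0.2) or high-dose replicates 1 or 2 (0.18 and 0.2). GLA was at 0.26 ± 0.07. GLA lost its call without vehicle replicates 1, 2 or 3 (0.23, 0.27 and 0.28) or high-dose replicates 1 or 3 (0.25 and 0.21). KIF20A was at -0.19 ± 0.05. KIF20A lost its call without vehicle replicates 1, 2 or 3 (-0.17, -0.21 and -0.2) or high-dose replicates 1 or 2 (-0.15 and -0.2). MKI67 was at -0.29 ± 0.08. MKI67 lost its call without vehicle replicates 1, 2 or 3 (-0.25, -0.31 and -0.31) or high-dose replicates 1, 2 or 3 (-0.31, -0.29 and -0.28). AC093484.3 and USP34-DT, antisense genes and so uncertain, were at -2.43 ± 0.66 and -0.62 ± 0.16. Their calls ended without vehicle replicates 1 or 2 (-1.9 and -2.4) or high-dose replicates 1, 2 or 3 (-2.53, -2.53 and -2.25) for the first, and without vehicle replicates 1 or 2 (-0.68 and -0.5) or high-dose replicates 1 or 3 (-0.5 and -0.69) for the other.

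By edgeR 291 genes changed at the high dose (1.76%), 152 upward and 139 downward, 6 and 3 of them at least 2-fold. The count was 47 and 151 without vehicle replicates 1 and 2 and 91, 135 and 100 without high-dose replicates 1, 2 and 3. It was 73 without the 4 libraries of lowest GC slope, 12 from the 6 libraries alone, 505 with no filter, 475 by DESeq2 and 1418 with the covariates. Between high and low dose 1 gene differed, GCNT3 (chromosome 15, 59594875 to 59640239), a glycosyltransferase gene, at 19.9 ± 1.31 against 14.7 ± 0.558 CPM (log2 fold change 0.43 ± 0.07, edgeR adjusted p = 0.00078), named after its value was seen, and the count was 0 without high-dose replicate 2. There 441 genes had an unadjusted p under 0.05, DESeq2 called 4, and edgeR called 70 with no filter, 11 with the covariates, 3 without the 4 libraries of lowest GC slope and 0 from the 6 libraries alone. NRF2 targets had 0 of 19 genes past edgeR's test between these doses (5 higher adjusted over the list alone; median 0.064, camera adjusted p = 5.18e-08) and genes of the G2 and M phase 0 of 18 (3 lower adjusted over the list alone; -0.11, 6.91e-13). Against the vehicle 11 genes changed at the medium and 96 at the low dose. The medium count was 0 without vehicle replicate 1 and 0 and 5 without medium-dose replicates 2 and 3. The low count was 0 and 63 without vehicle replicates 1 and 2 and 17, 14 and 26 without low-dose replicates 1, 2 and 3.

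Liriopis Tuber at 500 µg/mL changed 8 genes. The 6 largest rises were AL355987.4 (0.53 ± 0.11), UNC93B1, which moves Toll-like receptors to endosomes (0.43 ± 0.09), KDM3A (0.33 ± 0.06), MAT1A, which makes S-adenosylmethionine in hepatocytes (0.28 ± 0.05), NARF (0.25 ± 0.05) and GMCL1 (0.24 ± 0.04 on the log2 scale). AL355987.4, KDM3A and NARF also lay above the 3 vehicle libraries in all libraries of every other extract group. MT1X fell from 33.4 ± 1.66 to 21.2 ± 3.19 CPM (SD, n = 3; -0.66 ± 0.13), and the metallothionein list fell with 1 of 9 members past edgeR's test (6 fell and 1 rose adjusted over the list alone; median -0.661, camera adjusted p = 2.94e-07). MT2A, at 104 ± 28 against 197 ± 11.4 CPM, did not pass (edgeR adjusted p = 0.093). The edgeR adjusted p-values of the 7 named genes lay between 0.0046 and 0.04.

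Hypoxia targets were called upward with 1 of 16 members past edgeR's test (3 adjusted over the list alone; median 0.114, camera adjusted p = 8.89e-06), glycolysis genes with 0 of 16 (8 adjusted over the list alone; 0.146, 2.01e-06) and PPARA genes with 0 of 13, also adjusted over the list alone (0.132, 0.0171). Mitochondrially encoded mRNAs were called downward with 0 of 13, also adjusted over the list alone (-0.395, camera adjusted p = 1.17e-06, and adjusted p = 0.249 with an estimated correlation), as were ribosome biogenesis genes with 0 of 20 (2 adjusted over the list alone; -0.083, camera adjusted p = 0.00406, and adjusted p = 0.116 with an estimated correlation). The mitochondrial share of counts was 11.1% ± 1.46. Single omissions gave 1, 3 and 5 genes without vehicle replicates 1, 2 and 3 and 4, 0 and 4 without high-dose replicates 1, 2 and 3, and the calls of the 7 named genes each ended in some of these fits. That of AL355987.4 ended without vehicle replicates 1, 2 or 3 (0.56, 0.55 and 0.49) or high-dose replicates 1, 2 or 3 (0.54, 0.51 and 0.55). That of UNC93B1 ended without vehicle replicates 1 or 2 (0.36 and 0.43) or high-dose replicates 1, 2 or 3 (0.44, 0.51 and 0.35). That of KDM3A ended without vehicle replicates 1 or 2 (0.29 and 0.31) or high-dose replicate 2 (0.32). That of MAT1A ended without vehicle replicate 1 (0.24) or high-dose replicate 2 (0.24). That of NARF ended without vehicle replicates 1 or 3 (0.22 and 0.25) or high-dose replicates 1 or 2 (0.23 and 0.22). That of GMCL1 ended without vehicle replicates 2 or 3 (0.21 and 0.23) or high-dose replicate 2 (0.2). That of MT1X ended without vehicle replicates 1, 2 or 3 (-0.64, -0.7 and -0.64) or high-dose replicates 2 or 3 (-0.54 and -0.69). The count was 2 without the 4 libraries of lowest GC slope, 1 from the 6 libraries alone, 15 with the stricter filter, 55 by DESeq2, 346 with the covariates and 515 with no filter, with 2077 genes at an unadjusted p under 0.05.

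Between high and low dose of Liriopis edgeR called 0 genes (806 with an unadjusted p under 0.05, 0 by DESeq2, 125 by edgeR with no filter), and the metallothionein list was lower at the high dose with 0 of 9 past edgeR's test (7 lower and 1 higher adjusted over the list alone; median -0.611, camera adjusted p = 6.37e-10). Against the vehicle 5 genes changed at each of the other doses, named here after their values were seen. At the medium dose AL355987.4 (0.53 ± 0.11), IKBKB, a kinase of the NF-kB pathway (0.33 ± 0.06), and DHRS3, a retinal reductase (0.29 ± 0.06), rose, and RFX7 (-0.3 ± 0.06) and ZNF468 (-0.32 ± 0.06) fell. At the low dose KDM3A (0.33 ± 0.06), DHRS3 (0.32 ± 0.06) and TIA1, an RNA-binding protein of stress granules (0.21 ± 0.04), rose, and RNF4 (-0.22 ± 0.04) and PPP1R13B (-0.3 ± 0.05) fell. The medium count was 0 without vehicle replicate 1 or medium-dose replicates 2 or 3. The low count was 2 without vehicle replicate 1, 12 without low-dose replicate 1 and 1 without low-dose replicate 3, and 12 with replicate number as a block.

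**Figure D3:**
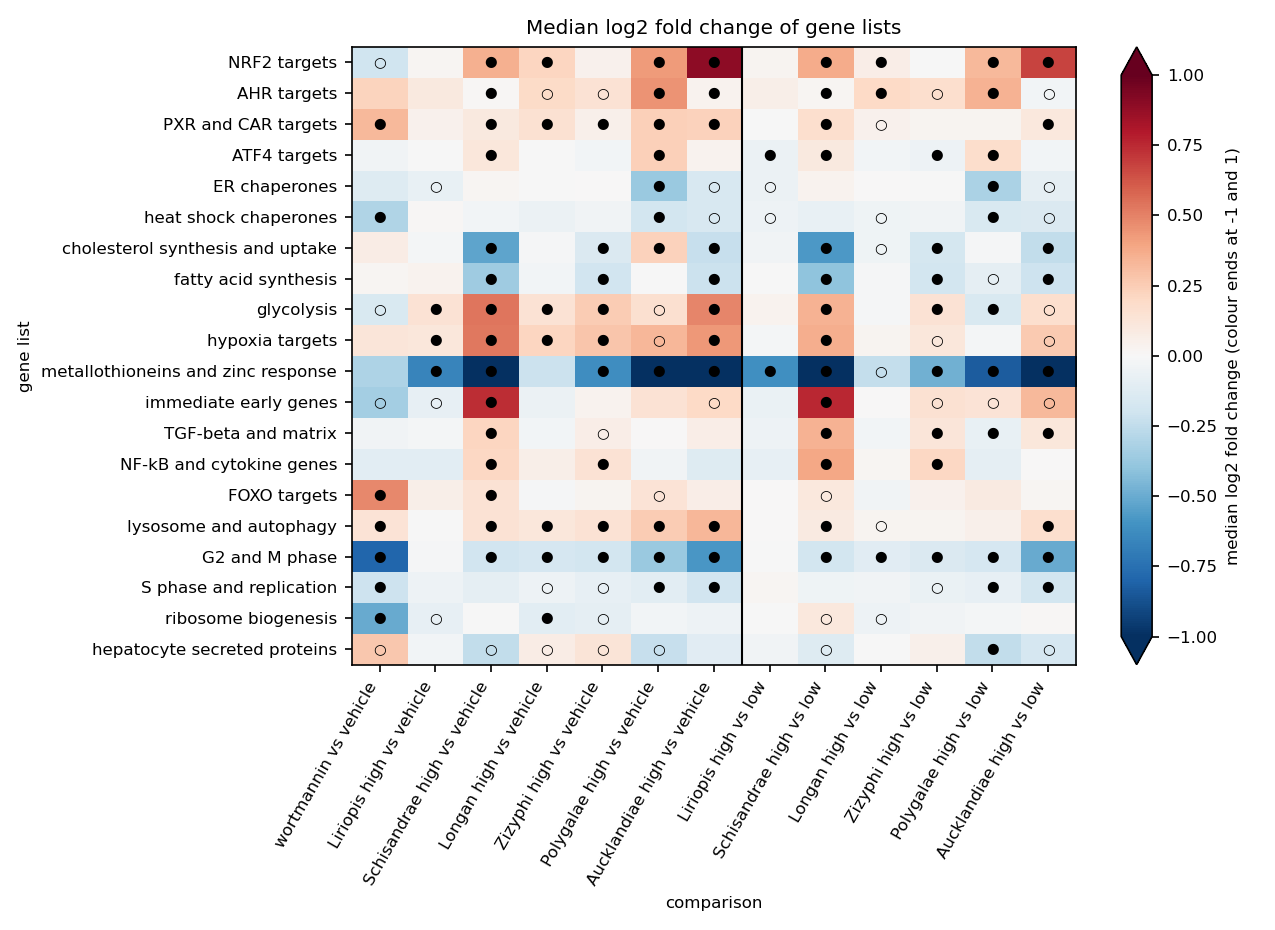
Median log2 fold change of a part of the tested gene lists (one line per list). Columns are wortmannin and the high doses against the vehicle, and high against low dose, with colour ending at -1 and 1. Filled circles mark camera calls that also hold with an estimated correlation. Open circles mark those with the preset correlation alone, such as the rise of hepatocyte secreted proteins with wortmannin (median 0.267).

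Across wortmannin and the high doses, camera called 114 of 245 list tests, of which 73 held with an estimated correlation, and between high and low dose 90 of 210, of which 53 held. Those that held against the vehicle are the lists described above without a second p. The other calls against the vehicle were lost, and brackets give the median, the camera adjusted p and the adjusted p with an estimated correlation. With wortmannin they were glycolysis (-0.152, 0.0459 and 0.407), acute phase proteins (0.169, 0.0222 and 0.442) and mitochondrial mRNAs (-0.49, 0.0163 and 0.562). With Aucklandiae they were heat shock chaperones (-0.163, 0.0254 and 0.252), ER chaperones (-0.164, 0.0197 and 0.237) and bile acid metabolism (0.217, 0.0488 and 0.072). Further ones with Aucklandiae were acute phase proteins (-0.22, 0.0163 and 0.425), immediate early genes (0.196, 0.0448 and 0.407) and nuclear respiratory chain subunits (0.218, 0.015 and 0.494). With Schisandrae they were hepatocyte secreted proteins (-0.244, 0.00154 and 0.391), acute phase proteins (-0.232, 8.74e-06 and 0.125) and mitochondrial mRNAs (-0.441, 0.00399 and 0.491). With Polygalae they were FOXO targets (0.14, 0.0233 and 0.103), glycolysis (0.162, 0.0123 and 0.299), acute phase proteins (-0.164, 0.00109 and 0.294) and iron handling (0.195, 0.0499 and 0.0843). With Zizyphi they were AHR targets (0.146, 0.0189 and 0.115), S phase and replication (-0.079, 0.0101 and 0.0875) and TGF-beta and matrix (0.064, 0.0409 and 0.0558). Further ones with Zizyphi were nuclear respiratory chain subunits (0.172, 1.43e-05 and 0.237), ribosomal proteins (0.135, 0.00202 and 0.6) and ribosome biogenesis (-0.087, 0.00127 and 0.072). With Longan they were AHR targets (0.194, 0.0281 and 0.143), hepatocyte secreted proteins (0.072, 0.00147 and 0.391), S phase and replication (-0.049, 0.044 and 0.194) and nuclear respiratory chain subunits (0.119, 0.000276 and 0.325). With Liriopis they were ER chaperones (-0.075, 0.0395 and 0.298), acute phase proteins (-0.094, 0.0171 and 0.43), immediate early genes (-0.085, 0.0161 and 0.325) and ribosomal proteins (-0.08, 0.0194 and 0.693). Of the 14 genes fixed in advance, IGFBP1 rose with wortmannin and 5 of the 6 high-dose extracts, all but Liriopis (0.54 ± 0.19, edgeR adjusted p = 0.23). These contrasts share the 3 vehicle libraries, and IGFBP1 lay above them in all libraries of the 18 extract groups, low doses and Liriopis included (at least 28.494 against at most 27.329 CPM). CYP1A1 rose in the same contrasts except Longan (0.29 ± 0.1, edgeR adjusted p = 0.11). CYP3A4, at 0.34 ± 0.0978 CPM with wortmannin and 0.124 ± 0.0761 CPM in the vehicle, passed with wortmannin (1.48 ± 0.53, edgeR adjusted p = 0.025), a call that ended without vehicle replicate 1 (1.02) or wortmannin replicate 3 (1.22). DDIT3, a stress-induced transcription factor, passed in 0 of these 7 contrasts by edgeR, with log2 fold changes from -0.31 to 0.21.

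To compare extracts without the vehicle, each extract's high minus low dose effect was set against the mean of the other 5. Camera called 95 of 210 list tests, 56 of them also with an estimated correlation. NRF2 targets stood above the other extracts with Aucklandiae (16 of 19 genes, 19 adjusted over the list alone; median difference 0.525, camera adjusted p = 5.75e-86), cholesterol genes below with Schisandrae (21 of 23, 21 below and 1 above adjusted over the list alone; -0.447, 3.78e-52) and ER chaperone genes below with Polygalae (8 of 17, 12 adjusted over the list alone; -0.292, 3.05e-22). AHR targets stood above with Polygalae (2 of 6, 3 adjusted over the list alone; 0.215, 2.29e-16). For PXR and CAR targets with Aucklandiae the median difference was -0.006 while the test called them upward (5.54e-05). Across the 16517 genes, which are not independent replicates, the Pearson correlation of these effects and of wortmannin's effect lay between -0.13 (Zizyphi with Polygalae) and 0.18 (Schisandrae with Aucklandiae) over 21 pairs, and the highest was 0.37 with the stricter filter.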

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

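The tests of SLC30A1, of wortmannin, of dose and of the order of Polygalae doses below were chosen after the result was seen, and the others before. The lists named next were picked out because an extract's change from low to high dose differed from the mean change of the other 5 extracts by camera, with the preset and with an estimated correlation. Values are medians of the difference on the log2 scale.

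Aucklandiae stood above the others in NRF2 targets (0.525), lysosome (0.153), bile acid (0.154) and PPARA genes (0.131). It stood below in G2 and M phase (-0.386), replication (-0.142) and cholesterol genes (-0.078). The test and the median differed in sign for PXR and CAR targets (-0.006) with Aucklandiae. Schisandrae stood above the others in immediate early genes (0.657), glycolysis genes (0.335), hypoxia targets (0.3), TGF-beta and matrix genes (0.29), NF-kB and cytokine genes (0.322), NRF2 targets (0.12), ATF4 targets (0.112), ribosome biogenesis genes (0.106) and ER chaperones (0.144) and stood below them in cholesterol synthesis and uptake genes (-0.447), fatty acid synthesis genes (-0.302), metallothionein and zinc response genes (-1.408), hepatocyte transcription factors (-0.229) and bile acid genes (-0.22). Polygalae stood above the others in cholesterol genes (0.21), AHR targets (0.215) and ATF4 targets (0.2). It stood below in glycolysis genes (-0.29), ER chaperones (-0.292), TGF-beta and matrix genes (-0.218), hypoxia targets (-0.196) and PPARA genes (-0.159). Zizyphi stood above the others in ER chaperones (0.075) and stood below them in NRF2 targets (-0.325), ATF4 targets (-0.076), iron handling genes (-0.133) and AHR targets (-0.042). Longan stood above the others in cholesterol (0.181), fatty acid synthesis (0.158), metallothionein (0.879) and G2 and M phase genes (0.104). Longan stood below in NRF2 targets (-0.17), immediate early (-0.347), glycolysis (-0.105) and TGF-beta and matrix genes (-0.053). Liriopis stood above in G2 and M phase (0.189), cholesterol (0.168), fatty acid synthesis (0.173) and replication genes (0.086) and hepatocyte transcription factors (0.128). It stood below in NRF2 (-0.32), ATF4 (-0.098), AHR (-0.016), PXR and CAR (-0.14) and hypoxia targets (-0.155). It also stood below in immediate early (-0.31), lysosome (-0.12) and TGF-beta and matrix genes (-0.126).

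More genes differed from the vehicle at the low Polygalae dose (2584) than at the medium dose (1926). Fits without each of the 9 libraries kept this order in 7. It turned without low-dose replicate 2 (1193 against 1987) and medium-dose replicate 1 (2643 against 2969), so a single library may account for it. Without vehicle replicate 1 the counts were 1208 and 1005, and without medium-dose replicates 2 and 3 they were 2662 and 867 and 2577 and 1075. With GC slope and structured RNA share as covariates they were 3587 and 2220, which argues against these as the whole source. Without the 4 libraries of lowest GC slope they were 1343 and 1172, and from the 6 libraries alone 1455 and 185. Of the 2584 genes, 8.44% also differed in the same direction from low-dose Aucklandiae. Both Polygalae doses share a code set, so this share says nothing on their order.

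Metallothionein genes fell at the high Schisandrae dose. Reads shared between their near-identical copies could not produce this, since the summed CPM of the 18 copies and pseudogenes fell too, with a log2 ratio of -1.84 between high and low dose (286 ± 41.3 to 79.9 ± 14.6 CPM, SD, n = 3). With GC slope and structured RNA share as covariates the median of the list was -2.167, which argues against GC content. SLC30A1, a zinc exporter that zinc induces with the metallothioneins, was at -0.76 ± 0.07 between the doses (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 5.2e-11), so a weaker zinc response remains a hypothesis, found and tested on the same data.

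Hypoxia targets lay above the vehicle in all 18 extract groups, with medians from 0.11 to 0.524 and a median over groups of 0.214. Without vehicle replicate 1 that median was 0.236, which argues against this library as the source. The list was called upward from low to high dose in 3 of the 6 extracts, which argues against dose as the whole cause. Of these, camera did not call Aucklandiae (adjusted p = 0.0683 with an estimated correlation) or Zizyphi (adjusted p = 0.0561 with an estimated correlation), and Schisandrae kept its call. In wortmannin the list was at 0.118 and was not called (camera adjusted p = 0.123), and wortmannin may act on these genes itself. This leaves open a difference between the code set of the vehicle and the others.

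The 6 libraries of a comparison were also divided in every other way into 3 and 3, with a fit of these 6 libraries alone. Pairs give the real count and the highest of the others, with the number of the 10 splits calling as many in brackets. Against the vehicle they were wortmannin 6022 and 0 (1), for the high doses Liriopis 1 and 0 (1), Schisandrae 2326 and 0 (1), Longan 12 and 2 (1), Zizyphi 173 and 0 (1), Polygalae 3795 and 0 (1) and Aucklandiae 4577 and 0 (1), for the medium doses Liriopis 4 and 4 (2), Schisandrae 332 and 0 (1), Longan 10 and 3 (1), Zizyphi 5 and 1 (1), Polygalae 185 and 1 (1) and Aucklandiae 70 and 2 (1) and for the low doses Liriopis 2 and 1 (1), Schisandrae 21 and 2 (1), Longan 11 and 1 (1), Zizyphi 12 and 8 (1), Polygalae 1455 and 0 (1) and Aucklandiae 36 and 3 (1). Between high and low dose they were Liriopis 0 and 82 (10), Schisandrae 1328 and 0 (1), Longan 0 and 2 (10), Zizyphi 3 and 38 (2), Polygalae 453 and 1 (1) and Aucklandiae 1525 and 0 (1). With 10 splits no share under 0.05 can arise. Other splits of the Liriopis and Zizyphi doses called more genes than the real ones (82 and 38), which points to structure among these libraries. So the 0 for Liriopis does not exclude a dose effect. Same-numbered Zizyphi libraries deviated together (r = 0.32, 0.55 and 0.16). The 3 other splits parting all 3 such pairs called 0 genes, and the 38 came from a split parting 1 pair. With the replicate block over all libraries the real Zizyphi count was 60, and 78 within code sets.

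For the gene lists and the similarity the libraries were regrouped at random 100 times, the real grouping included, with a fit of the libraries involved alone. Lists called against the vehicle were 108 with the real grouping, and with others 62 in the median and at most 115, of which 2 groupings, the real one included, called as many, and between high and low dose 92, with others 32 in the median and at most 53 (1 as many). Lists differing between extracts were 96, with others 34 in the median and at most 68 (1 as many). For these totals chance can be excluded at a share of 0.05. Single lists were not tested so, and other groupings called many. The highest correlation between effects was 0.18 and at most 0.22, with 11 groupings as high, so chance cannot be excluded for it. Draws for the dose, extract and similarity results were raised to 100 after a run with fewer was seen, and no reading changed.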

How the results depend on the processing

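Of 198 values of genes picked by the naming rule, none turned direction in a setting fitted for them. Without the 4 libraries of lowest GC slope 43 lost their call, from only the 6 libraries 40, with no filter 10, with DESeq2 7 and with the covariates 2. With no filter 11 gained a call, with the covariates 9 and with DESeq2 6. With RLE normalization, the replicate block and the stricter filter, which left 195 of the values, 0 changed their call. The settings with covariates and without the 4 libraries were chosen after the data were seen. Fits of 6 libraries use their own spread, and fewer libraries did not always lower counts (wortmannin 6022). Counts and correlations that moved by over 1.5 times follow by setting, with no cause tested.

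With DESeq2, 15 of 25 results stayed within 1.5 times and the others were Liriopis high 55, Liriopis medium 35, Liriopis low 39, Schisandrae low 40, Longan high 475, Longan medium 51, Longan low 228, Zizyphi medium 272, Zizyphi low 542 and Longan high against low 4. With RLE normalization, 28 of 29 stayed, and others were Schisandrae low 6. With no filter, 15 of 28 stayed, and others were Liriopis high 515, Liriopis medium 292, Liriopis low 260, Schisandrae medium 752, Schisandrae low 354, Longan high 505, Longan medium 290, Longan low 454, Zizyphi medium 438, Zizyphi low 697, Liriopis high against low 125, Longan high against low 70 and Zizyphi high against low 207. With the stricter filter, 25 of 29 stayed, and others were Liriopis high 15, Liriopis medium 8, Liriopis low 9 and the highest similarity 0.37. From only the 6 libraries, 10 of 25 stayed, and others were Liriopis high 1, Liriopis low 2, Schisandrae low 21, Longan high 12, Longan low 11, Zizyphi high 173, Zizyphi medium 5, Zizyphi low 12, Polygalae medium 185, Polygalae low 1455, Aucklandiae medium 70, Aucklandiae low 36, Longan high against low 0, Zizyphi high against low 3 and Aucklandiae high against low 1525. With GC slope and structured RNA share as covariates, 9 of 28 stayed, and others were Liriopis high 346, Liriopis medium 69, Liriopis low 779, Schisandrae high 4177, Schisandrae medium 1175, Schisandrae low 174, Longan high 1418, Longan medium 848, Longan low 685, Zizyphi high 1442, Zizyphi medium 1112, Zizyphi low 1875, Aucklandiae medium 2689, Aucklandiae low 2115, Schisandrae high against low 2797, Longan high against low 11, Zizyphi high against low 216, Polygalae high against low 1307 and Aucklandiae high against low 3718. Without the 4 libraries of lowest GC slope, 12 of 28 stayed, and others were Liriopis high 2, Liriopis medium 0, Liriopis low 0, Schisandrae medium 145, Schisandrae low 0, Longan high 73, Longan medium 0, Longan low 0, Zizyphi high 230, Zizyphi medium 2, Zizyphi low 52, Polygalae medium 1172, Polygalae low 1343, Aucklandiae medium 203, Aucklandiae low 223 and Longan high against low 3. In camera with an estimated correlation, 0 of 3 stayed, and others were lists against the vehicle 73, lists between doses 53 and lists between extracts 56. With the replicate block, 27 of 29 stayed, and others were Liriopis low 12 and Schisandrae low 25. With the replicate block within each code set, 5 of 6 stayed, and others were Longan high against low 2.

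Libraries with the same replicate number and code set had a mean correlation of deviations of 0.1, against -0.046 for other numbers of the set. Neither the replicate block nor the block within code sets moved a further count by over 1.5 times. The latter was fitted only for the high against low counts. With the block, wortmannin was 5429, Schisandrae high against low was 1682.

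With each library left out in turn the values ran as follows: wortmannin 4308 to 4978, Liriopis high 0 to 5, Liriopis medium 0 to 6, Liriopis low 1 to 12, Schisandrae high 1861 to 2287, Schisandrae medium 117 to 528, Schisandrae low 0 to 7, Longan high 47 to 234, Longan medium 0 to 10, Longan low 0 to 111, Zizyphi high 195 to 681, Zizyphi medium 1 to 131, Zizyphi low 26 to 288, Polygalae high 2200 to 2987, Polygalae medium 867 to 2969, Polygalae low 1193 to 2526, Aucklandiae high 3188 to 3915, Aucklandiae medium 303 to 1169, Aucklandiae low 121 to 771, Liriopis high against low 0 to 0, Schisandrae high against low 1233 to 1348, Longan high against low 0 to 1, Zizyphi high against low 23 to 62, Polygalae high against low 370 to 604, Aucklandiae high against low 1885 to 2185, lists against the vehicle 105 to 115, lists between doses 85 to 98 and lists between extracts 93 to 103. Group means then rest on 2 libraries in 1 arm, and depth limits calls among genes with few counts.

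Of 1188 values of these genes with a library left out, 1019 kept their side of the threshold, 167 lost it and 2 gained it.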
